A study of Rattus norvegicus with 3 samples.

How the data were processed

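RNA sequencing was done on 3 libraries of adult rat liver, from healthy animals, from animals given saline and partial hepatectomy, and from animals given etanercept and partial hepatectomy. Per the series description, RNA of 3 rats was pooled in each group and sequenced on an Ion Torrent instrument. Per the labels' protocols, total RNA was isolated with a mirVana kit, ribosomal RNA was removed with a RiboMinus kit, and libraries were made with the Ion Total RNA-Seq Kit v2. Removal of ribosomal RNA keeps transcripts without a poly(A) tail, so gene counts can include other RNA classes beside messenger RNA. TopHat2 2.0.13 and HTSeq 0.6.1 are named in the submitters' processing notes. The genome build, annotation release and strand setting of the counting are not given in the sources used here. It is therefore not known whether reads antisense to a gene were counted for it. Reads in more than 1 gene, and reads aligned to several places, were tallied apart from the gene counts. Overlapping genes and near-identical copies can thus be undercounted.

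The deposited values are raw read counts per Ensembl rat gene identifier, as whole numbers and not normalized. Each file lists the same 26404 identifiers and 5 summary rows that name no gene. Of these identifiers, 8965 had no read in any library. The summary rows for low quality and unaligned reads were 0. Those for reads in no gene and in more than 1 gene held 1503824 and 55062 reads in the healthy library, 739948 and 29748 in the saline library, and 13508225 and 294622 in the etanercept library. These rows stayed out of library sizes and gene comparisons. Shares of uniquely aligned reads were taken over gene reads, reads in no gene and reads in more than 1 gene, together 7552720, 3414848 and 17442733. The row for reads aligned to several places was left out of every share, since it can list a read more than once. It held 23930072, 14151091 and 36628956 entries in the healthy, saline and etanercept libraries. In each library that is more than all uniquely aligned reads, so the shares do not describe all aligned reads.

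The identifiers could not be joined to gene names. The reference gene table used here gave an Ensembl identifier for 0 of its entries, and 0 of the 26404 identifiers matched it. Genes are therefore given by identifier, without name or coordinates, and 33 gene lists fixed before the data were examined were not scored. Among genes meeting the size rule, the gene named in each direction in saline against healthy and in etanercept against saline is the one whose 95% counting bound nearest to no change lay farthest from it. This narrows the rule fixed beforehand, which would have named 8 symbols per direction, members of the gene lists and the genes taking most reads; shares of the latter are given without identifiers.

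With 1 library per group no test was possible and no p-value was computed. Levels are CPM, counts scaled by the effective library size from TMM (edgeR 4.0.16 in R 4.3.3). The TMM factors were 0.896 for the healthy, 1.22 for the saline and 0.912 for the etanercept library. A fold is the ratio of scaled counts after adding a pseudocount of 0.5. A gene was called when the fold was at least 2 in either direction and the higher library had at least 5 CPM, which is 26.9, 16.2 and 16.6 counts in the healthy, saline and etanercept libraries. A count of 0 allows a level of up to 3 counts, which is 0.559, 0.927 and 0.904 CPM. The fold of a gene with 0 counts in a library depends on the pseudocount. The 95% interval of a fold is the exact Clopper-Pearson interval of the share of counts (scipy 1.17.1, Python 3.11.15). Intervals and floors cover counting error only. They leave out variation between animals, which pooling hides, and between library preparations.

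The calling rule was tested on simulated data. Libraries were drawn as Poisson counts from the mean levels of the real ones, with 200 genes changed by known folds. Of 50 genes changed 3-fold between saline and healthy 100% were called, and of 50 changed 1.5-fold 12% were called. In etanercept against saline the shares were 100% at 3-fold, 96% at 4-fold and 98% at 8-fold, and in etanercept against healthy 94% at 3-fold and 4-fold and 100% at 8-fold. Of the 9413 unchanged genes tested in saline against healthy 59 were called. In etanercept against saline 90 of 9429 unchanged genes were called, and in etanercept against healthy 53 of 9437. The intervals covered the true fold for 95.6% of genes in saline against healthy. The simulated libraries hold counting error only, so false calls between real libraries can be more frequent and coverage lower.

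Overlaps of calls and correlations of folds between comparisons that share a library were set beside 100 simulations of unchanged libraries. For the correlations, and for the position of etanercept among the genes called between saline and healthy, the reads of the shared saline or healthy library were also split at random into 2 equal parts, averaged over 20 draws. The overlaps were not recomputed with split reads. Equal-depth values came from random thinning without replacement. Alternatives were DESeq2 1.42.0 median-of-ratios scaling, total-read scaling, total reads without the 20 most abundant genes, floors of 1 and 20 CPM and none, a pseudocount of 5, a fold of at least 3, and a counting interval wholly beyond 1.5-fold. Equal depth, and scaling from the healthy and saline libraries alone, were added after seeing the data.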

Results

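Messenger and other RNA was profiled by sequencing in 3 libraries of adult rat liver. The first library came from healthy, untreated animals. The other two came from livers taken 32 hours after partial hepatectomy, an operation in which part of the liver is removed and the remnant regrows. One hepatectomy group had received saline in a volume of 1 ml. The other had received etanercept at 9 mg/kg in the same volume, 16 to 18 hours before surgery. Etanercept is a fusion protein built on a TNF receptor; it binds TNF and keeps it from its receptors on cells. RNA of 3 rats was pooled within each group before sequencing, so each group was represented by 1 library. No spread between animals could be estimated, and no p-value is given. Every difference below is a difference between libraries with no replicate check, and every interval covers counting error only.

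The libraries differed in depth and in where their reads fell. Reads assigned to genes numbered 5993834 in the healthy library, 2645152 in the saline library and 3639886 in the etanercept library. At least 1 read was found for 15966, 14631 and 13036 gene identifiers, respectively, of 26404 listed. Of the uniquely aligned reads, 79.4% fell in 1 gene in the healthy library and 77.5% in the saline library, against 20.9% in the etanercept library. Reads in no annotated gene made up 19.9%, 21.7% and 77.4% of uniquely aligned reads in the healthy, saline and etanercept libraries. The exact 95% binomial (Clopper-Pearson) intervals of these shares reach at most 0.044 percentage points to either side. When all libraries were thinned at random to 2645152 gene reads, the healthy library detected 14427 genes and the etanercept library 12708, as means over 20 draws, against 14631 in the saline library.

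**Figure D1:**
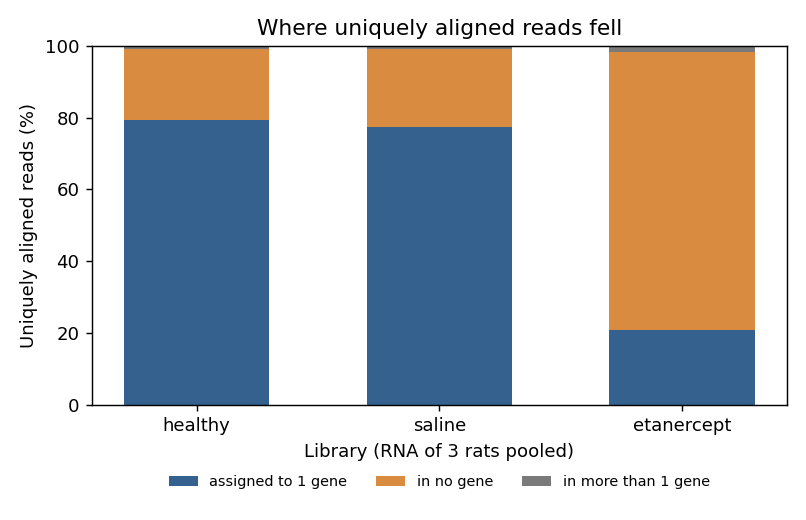
Share of uniquely aligned reads (%, vertical axis) assigned to 1 gene, to no gene or to more than 1 gene in the healthy, saline and etanercept libraries, each a pool of 3 rats. Reads in no gene make up 77.4% of the etanercept library, against 19.9% in the healthy and 21.7% in the saline library.

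The saline library was compared with the healthy library to describe the liver transcriptome 32 hours after hepatectomy. The healthy animals were untreated, and no library came from a sham operation. Regrowth therefore cannot be told apart from other effects of the operation or of the saline. Of 9755 genes with at least 5 CPM (counts scaled to the effective library size) in the higher library, 909 were at least 2-fold higher and 942 at least 2-fold lower in the saline library, together 19.0%. Differences of at least 4-fold were more often upward, with 338 genes higher and 153 lower. Among the genes at least 2-fold higher, 108 had at most 3 counts in the healthy library, and 24 of these had none. Among those lower, 38 had at most 3 counts in the saline library and 1 had none. The files list Ensembl gene identifiers without names, so the genes are not named here.

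The gene whose increase was best separated from counting error was ENSRNOG00000028896. It had 2 counts (0.372 CPM) in the healthy library and 781 counts (241 CPM) in the saline library, a ratio of 519 with a 95% counting interval of 179 to 5362. The etanercept library also held this transcript at a high level, 394 CPM. The clearest decrease was that of ENSRNOG00000008050, which stood at 378 CPM in the healthy library and 6.49 CPM in the saline library. Its level was 57.0-fold lower in the saline library, with an interval of 38.0 to 94.4. In the etanercept library it was 8.73 CPM, 42.6-fold below healthy with an interval of 30.1 to 64.9.

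Abundant transcripts took a smaller part of the saline library than of the healthy library. The most abundant gene was the same in both and took 11.0% of gene reads in the healthy library (95% interval 11.0 to 11.1) and 6.92% in the saline library (6.89 to 6.95). At least 50% of all gene reads came from 102 genes in the healthy library and from 192 genes in the saline library. Of the 103 genes with a mean of at least 1000 CPM over the libraries, 31 were at least 2-fold lower and 3 at least 2-fold higher in the saline library, and their median log2 fold was -0.63. Of the 1262 genes between 100 and 1000 CPM, 221 were lower and 43 higher, with a median of -0.31. The median was -0.07 among the 3997 genes between 20 and 100 CPM and 0.04 among the 3982 genes between 5 and 20 CPM.

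The split between higher and lower genes depended on how the libraries were scaled. Scaling by total gene reads instead of the trimmed mean of M-values (TMM) shifted all saline over healthy log2 folds by 0.45, and 1987 genes were then higher and 363 lower. The share of higher genes among those called was 49.1% with TMM and 84.6% with total reads. Under total reads the median for genes between 100 and 1000 CPM changed sign, to 0.14, and that of genes of at least 1000 CPM was -0.18. In the 100 to 1000 CPM class 9.11% of genes were then higher and 6.66% lower. Among genes of at least 1000 CPM the shares were 8.74% and 15.5%. Scaling moves every fold by the same amount, so it cannot alter the differences between the medians of these classes.

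**Figure D2:**
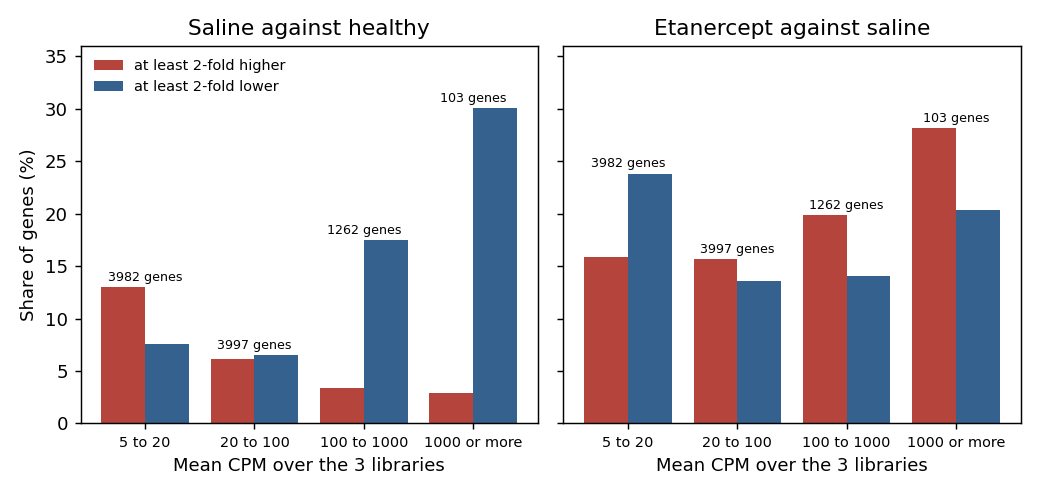
Share of genes (%, vertical axis) at least 2-fold higher (red) or lower (blue) in the saline library against healthy (left) and in the etanercept library against saline (right), by mean CPM over the 3 libraries (horizontal axis), after TMM scaling. In the saline library 30.1% of genes of at least 1000 CPM were lower and 2.91% higher; against saline, the etanercept library had 20.4% lower and 28.2% higher in that class. Total-read scaling raises the higher share on the left and the lower share on the right. In the saline library it gave 15.5% lower and 8.74% higher among genes of at least 1000 CPM.

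The comparison of the etanercept library with the saline library addressed the effect of binding TNF before hepatectomy. Of 9991 genes tested, 1827 were at least 2-fold higher and 1915 at least 2-fold lower in the etanercept library, together 37.5%. Differences of at least 4-fold were found upward in 624 genes and downward in 657. Among the lower genes, 259 had at most 3 counts in the etanercept library and 91 had none. The number called was 2.02 times that between the saline and healthy libraries. Because this library also had 77.4% of its uniquely aligned reads outside genes, treatment and library make-up cannot be separated in this comparison.

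The largest separated increase was that of ENSRNOG00000045015. It stood at 9.31 CPM in the healthy library, 4.94 CPM in the saline library and 6303 CPM in the etanercept library, where it had 20930 counts. The ratio of etanercept to saline was 1236, with a counting interval of 785 to 2231. ENSRNOG00000045589 showed the clearest decrease, from 225 CPM (727 counts) in the saline library to 2.41 CPM (8 counts) in the etanercept library. It was 87.8-fold lower, with an interval of 47.1 to 217, and had been at 170 CPM in the healthy library. Between the healthy and saline libraries the first was 1.84-fold lower in saline (interval 1.05 to 3.54) and the second 1.32-fold higher (1.20 to 1.46).

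A different gene led the etanercept library, while gene reads were about as concentrated as in the healthy library. The 100 most abundant genes by mean CPM took 48.4% of etanercept, 47.9% of healthy and 42.3% of saline gene reads. The most abundant gene of the etanercept library took 6.47% of its gene reads (95% interval 6.44 to 6.49), against 0.411% in the healthy and 0.399% in the saline library. The gene that led the other libraries, with 11.0% and 6.92% there, took 2.87% of the etanercept reads. At least 50% of the gene reads came from 95 genes, against 102 in the healthy library. Genes of at least 1000 CPM were called in both directions, with 29 higher and 21 lower of 103, and their median log2 fold against saline was 0.01. This class is set by the mean over the 3 libraries, so genes high in the etanercept library alone can enter it. Total-read scaling turned this class to 25.2% higher and 33.0% lower, with a median of -0.41. With total-read scaling all etanercept over saline log2 folds shifted by -0.42, giving 1092 higher and 3204 lower genes. The share of higher genes among those called was then 25.4%, against 48.8% with TMM.

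Genes called between the etanercept and saline libraries were also set against healthy. Of the 1827 higher genes, 979 (53.6%) had saline and healthy levels within 1.5-fold of each other, and 1381 were also at least 2-fold above healthy. Of the 1915 lower genes, 1132 (59.1%) had saline and healthy levels within 1.5-fold, and 1370 were also at least 2-fold below healthy. Over all 9991 genes tested, saline and healthy lay within 1.5-fold for 60.6%, and etanercept was at least 2-fold above healthy for 22.1% and below for 21.6%. Both comparisons use the same etanercept library. Independent lists would share 416 higher and 379 lower genes among the 9713 genes tested in both. Counting error alone gave means of 5.68 and 7.87 in the simulations. Unchanged libraries give far shorter lists of called genes than the real ones, so these means are no expectation for lists of the real lengths. The simulations also leave out variation between animals and preparations, through which the shared library can still add to the excess.

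The etanercept and healthy libraries differed most. Of 10069 genes tested, 2210 were at least 2-fold higher and 2417 at least 2-fold lower in the etanercept library, together 46.0%. The rank correlation of CPM across 10347 genes was 0.89 between saline and healthy, 0.79 between etanercept and saline, and 0.73 between etanercept and healthy; genes are not independent replicates. The 103 genes of at least 1000 CPM had a median log2 fold of -0.59 against healthy, with 41 lower and 29 higher. The share of uniquely aligned reads in no gene, 77.4% against 19.9%, differs between these libraries as well.

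Both hepatectomy libraries shared many differences from the healthy library. Of the 909 genes higher in the saline library, 544 (59.8%) were also at least 2-fold above healthy in the etanercept library, and 27 were at least 2-fold below. Of the 942 genes lower in the saline library, 601 (63.8%) were also lower in the etanercept library and 51 were higher. Among the 7904 genes not called between saline and healthy, 14.1% were higher and 22.6% lower in the etanercept library. Among the 9477 genes tested in both comparisons, 753 were higher in saline and 1709 in etanercept, and 942 and 2417 were lower. Independent lists of these lengths would share 136 higher and 240 lower genes. Both comparisons use the same healthy library. In 100 simulations of unchanged libraries, counting error alone gave a mean of 2.71 shared higher and 2.07 shared lower genes. Unchanged libraries give short lists, however. In the test of the calling rule 59 unchanged genes were called in saline against healthy and 53 in etanercept against healthy. Overlaps of lists that short could not approach the observed ones, so the simulated means are no expectation for lists of the real lengths. The simulation also leaves out variation between animals and between library preparations, so part of the excess may come from the shared library.

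**Figure D3:**
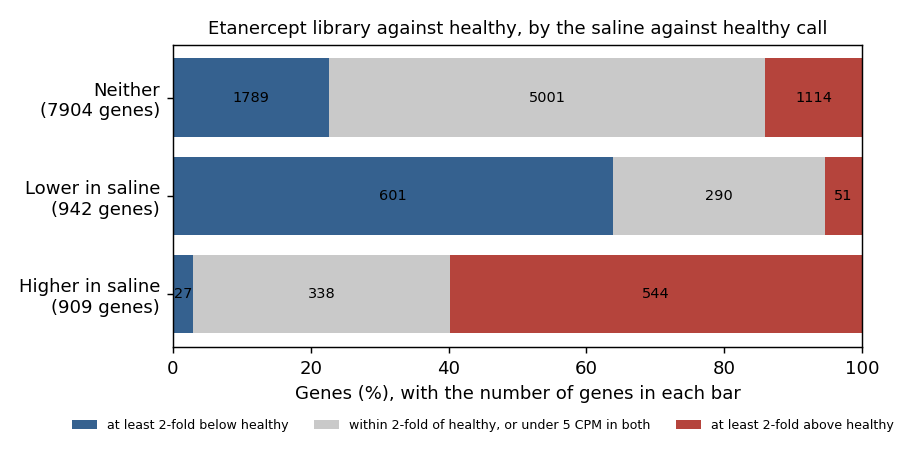
Genes higher, lower or neither in the saline library against healthy (rows), divided by whether the etanercept library was at least 2-fold below healthy (blue), at least 2-fold above healthy (red) or neither (grey), as a share of each row (%, horizontal axis) with the number of genes in each bar. Of the 909 genes higher in saline, 544 were also higher in etanercept; of the 942 lower, 601 were also lower.

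The design also asks whether etanercept moved the differences between saline and healthy back towards healthy. Of the 909 genes higher in the saline library, 247 (27.2%) were at least 2-fold lower in the etanercept than in the saline library and 116 (12.8%) were at least 2-fold higher. Genes not called between saline and healthy were lower in 19.4% and higher in 13.4%. Of the 942 genes lower in the saline library, 179 (19.0%) were higher in the etanercept library and 135 (14.3%) were lower still. Total-read scaling lowers every etanercept over saline fold and also redraws the lists of called genes. Of the 363 genes lower in saline in that scaling, 17.9% were higher and 21.2% lower in etanercept than in saline. For the 7581 genes not called in that scaling the shares were 7.61% and 30.6%. With TMM the median log2 fold of etanercept over saline was -0.28 for the genes higher in saline and 0.02 for those lower in saline. Both comparisons use the saline library, so chance counts there push the folds in opposite directions. With its reads split at random into 2 equal parts, each serving 1 comparison, 23.3% of the genes higher in saline were lower in etanercept and 15.4% higher. Of the genes lower in saline, 16.8% were then higher in etanercept and 17.4% lower. Of the genes not called, 14.1% were higher and 18.7% lower. The medians in this split were -0.22 for the genes higher in saline and -0.08 for those lower in saline. Variation between animals is not in these values, so a difference of this size cannot be assigned to the treatment.

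Across 10347 genes the etanercept over saline fold had a Pearson correlation of -0.07 with the saline over healthy fold. Unchanged libraries simulated with counting error gave -0.56, because their only covariance comes from the saline library. The covariance was -0.110, against -0.045 in the simulation, a difference of -0.065. With the saline reads split in this way the correlation was -0.01 and the covariance -0.022. The split removes shared counting error directly and leaves a smaller value than the -0.065 from the simulation. The -0.065 is therefore not taken as movement back towards healthy. For saline over healthy and etanercept over healthy the correlation was 0.55, against 0.37 in the simulation. The covariance was 1.10, against 0.026 in the simulation, a difference of 1.07. With the healthy reads split, that correlation was 0.49.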

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

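The tests of low counts, of library make-up and of an even background were chosen after the results were seen; the tests of abundant genes, duplicate reads and scaling were set before theirs were computed.

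Reads outside the gene counts were above the healthy level in both hepatectomy libraries. Reads in no gene made up 21.7% of uniquely aligned reads in the saline library and 77.4% in the etanercept library, against 19.9% in the healthy library. Reads in more than 1 gene made up 0.871% and 1.69%, against 0.729%. Relative to gene reads, reads in more than 1 gene were 8.09% in the etanercept library, 1.12% in the saline and 0.919% in the healthy library. Opposite calls against healthy were found for 78 genes, of which 27 were higher in saline and lower in etanercept and 51 the reverse. Independent lists would give 362 such genes. Both comparisons use the same healthy library, which by itself makes opposite calls rarer, so that value is not one for unchanged libraries. With 1 library per group the difference was not tested.

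The share of reads outside genes in the etanercept library is the pattern most in need of a second look. A candidate explanation is an even background of reads over the genome, such as from DNA. It would put reads into genes that are silent in liver, and at equal depth the etanercept library had a read for 5.59% of the 10438 genes at 0 in the healthy library (95% interval 5.16 to 6.05). The saline library had one for 9.64% (9.08 to 10.2), so the excess over saline that an even background predicts was not seen. The comparison has a limit, because the etanercept library detected fewer genes at equal depth, which by itself lowers this share. An even background would, however, add reads to undetected genes and so raise detection. Yet 13036 of 26404 identifiers had a read in the etanercept library, beside 13508225 reads in no gene. In this library these values argue against an even background as the source of most reads outside genes. A small background is not excluded. Reads from introns, from unannotated transcripts or counted on another strand setting were not tested, and an effect of etanercept remains open as well.

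The etanercept library detected fewer genes than the saline library at equal depth, 12708 against 14631. A few abundant genes do not account for this, because with the 100 most abundant genes of each library left out and equal totals it still detected 1797 genes fewer than saline. Duplicate reads of few molecules could also lower detection. Among 1579 genes expected to have 1 to 3 counts from their share of healthy gene reads, 54.7% had none in the etanercept library against 27.9% in the saline library. The share with 9 or more counts was 15.1% (13.4 to 17.0) against 12.0% (10.4 to 13.7), intervals that overlap, so duplicates stay open beside a real loss of weakly expressed transcripts. This expectation was scaled by total gene reads. That scaling puts log2 folds over healthy 0.45 above their TMM values for saline and 0.03 above for etanercept. It can thus lower the saline share with no counts and raise its share with 9 or more, so both contrasts depend on the scaling.

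More genes differed between etanercept and saline than between saline and healthy. Counting error at low counts is argued against, since with counting intervals wholly beyond 1.5-fold 2986 genes were still called, against 1396 for saline and healthy. Among 1365 genes with a mean of at least 100 CPM the called share was 35.0%, against 21.8% for saline and healthy. That is a gap of 13.2 percentage points, but the mean includes the etanercept library. Genes high in that library alone enter the class and can widen the gap. Scaling is argued against as well: the ratio of the numbers called was at least 1.83 under the 4 scalings tried. The make-up of the etanercept library and the etanercept treatment cannot be told apart, because 1 library carries both and its share of reads outside genes lay 55.8 percentage points above that of the saline library.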

How the results depend on the processing

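Equal depth and scaling from healthy and saline alone were chosen after seeing the data; all other alternatives were fixed before the data were examined. Of 68 alternative values of the numbers of genes, their overlap and the correlation, 37 stayed within 1.5 times the reported number or within the interval of the correlation. All 16 alternative folds of the 4 named genes kept their direction and lay within their counting intervals. Numbers are given as higher and lower. Total-read scaling gave 1987 and 363 for saline against healthy and 1092 and 3204 for etanercept against saline. Without the 20 most abundant genes in the totals these were 1767 and 415, and 1189 and 2986. A floor of 1 CPM gave 1562 and 1510 for saline against healthy and 3015 lower for etanercept against saline. A floor of 20 CPM gave 368 and 582, 1180 and 905, and 1350 and 1361 for saline against healthy, etanercept against saline and etanercept against healthy. No floor gave 2701 and 2426, 3185 and 4893, and 3464 and 4882. A fold of at least 3 gave 475 and 302, 961 and 1001, and 1311 and 1367. Stricter floors test fewer genes and a larger fold calls fewer by construction. Total-read scaling moved the saline library relative to the other two; the cause of that offset was not tested. A floor of 20 CPM also gave an overlap of 611 genes, against 1145, and a correlation of -0.025. At equal depth saline against healthy gave 967 and 1055, and without the etanercept library in the scaling 988 and 908. With total-read scaling, which also redraws these lists, 43.2% of the 1987 genes higher in saline were also higher in etanercept. Of the 363 genes lower in saline, 72.7% were also lower. In that scaling 40.7% of the genes higher in saline, and 30.6% of those not called, were lower in etanercept than in saline. Gene list medians were not run, since the identifiers could not be joined to symbols. No paired analysis was possible because each group had 1 library. Depth limits weakly expressed genes most: 3 counts correspond to 0.927 CPM in the saline library.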

Other observations

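Genes near the detection floor in the healthy liver were examined after the data were seen. Of 13837 genes with at most 3 counts in the healthy library, 108 reached at least 5 CPM in the saline library and 203 in the etanercept library. Of the 108, 91 were among the 203, where independent lists drawn from the 13837 genes would share 1.58. That expectation counts genes silent in every library, so it lies below what a list of genes active in liver would give, and both lists use the same healthy library. With total-read scaling the numbers were 128, 182 and 96. Another 62 genes reached 5 CPM in the etanercept library with at most 3 counts in both other libraries, and 8 genes did so in the saline library alone.

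In the opposite direction, 9003 genes stood at 5 CPM or more in the healthy library. Of these, 38 had at most 3 counts in the saline library and 308 in the etanercept library, and 19 were in both lists, against 1.30 for independent lists. Both lists start from the same healthy library, and genes near 5 CPM can reach the floor more easily in either. The value for independent lists is therefore not one for unchanged libraries. With 308 genes against 38, loss to the detection floor was found for more genes in the etanercept library, which also detected fewer genes at equal depth.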
